A study of Homo sapiens with 6 samples.

How the data were processed

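Messenger RNA splicing was measured by RNA sequencing of total RNA from MCF-7 cells, with 3 libraries titled sh and 3 titled u6. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V10 kit. The submitters' processing notes name HISAT2, HTSeq, SAMtools and R 3.2.0, with no role or order, and the build mm10, a mouse assembly. The files contradict that build: per the file headers and columns, chromosomes are human RefSeq sequences of GRCh38, and 91.4% of skipped exons shared a boundary with GENCODE release 29 on that assembly. Coordinates are given as in the files, 1-based, on GRCh38. The program that made the splicing tables is not given in the sources used here. Their columns, per the file headers, follow the junction-read output of a splicing event caller.

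For each of 5 event types the authors deposited a full table and a filtered list. The deposited counts of inclusion and skipping junction reads, and the deposited inclusion level, a fraction from 0 to 1 corrected for the lengths of both forms, join the 3 libraries of a group in 1 cell. The p-value and adjusted p-value of each event were deposited by the authors and are used as deposited, as is the difference of mean inclusion levels, which can be negative. The place of a library in a cell was not tied to a title, so libraries are numbered by place. The alternative 5' splice site table was held in part: 689 complete events on 7 chromosomes, with 1 incomplete row left out. No column of per-sample values in the full tables was left unused. The per-library values in the filtered list of alternative 5' splice sites were not tested. Events of that list outside the held part of the table, the SRSF2 one included, therefore have no limma test here.

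Events with at least 10 junction reads on average per library and both forms present in at least 1 library were tested, on log2 of the inclusion over skipping reads with a pseudocount of 0.5 reads on each. Form lengths were left out of this ratio. They are constant for an event and cancel between groups here, where the pseudocount is added to the reads. In the written design it is added after division by length, where lengths do not cancel, and that form was not run. Because libraries are joined in cells, the test was otherwise the one fixed beforehand for that case. It was limma 3.58.1 in R 4.3.3, with robust empirical Bayes and a variance trend. The written design names a trend on junction depth without saying of which form. The depth of the rarer form was chosen before any test was run, and total junction depth, the plainer reading, was added as an alternative after the data were seen. A call needed a Benjamini-Hochberg adjusted p below 0.05 within the event type and a difference of mean inclusion levels of at least 0.1. Fold changes on this log2 scale understate changes of forms with few reads. The junction depth of 11749153 to 15374949 reads over skipped exon events per library limits precision most for events near the minimum. Exact 95% binomial intervals of direction shares describe counting error only, and events of 1 gene are not independent.

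The test was tried on simulated data made from the real depths, with a beta-binomial spread that varied between events and 200 changed events. Changes were planted only in events with intermediate inclusion levels and at least 20 junction reads on average, so recovery in other events is not known. Of skipped exons (34146 events), 34% of changes of 0.2 and 65% of changes of 0.3 were recovered, with 8.3% false calls. For retained introns (1778 events) these shares were 40%, 83% and 0.8%, and for alternative 3' splice sites (5908 events) 42%, 82% and 0%. With no changed event, 2 skipped exons, 0 introns and 2 alternative 3' splice sites were called. Splits of the real libraries other than the real one called 2 to 14 skipped exons. The share of false skipped exons may therefore be higher than 8.3%. Before the minimum difference was asked for, 88 unchanged skipped exons had an adjusted p below 0.05 in the simulation with changed events, and 56 in that with none. With the trend on total junction depth, 0% of changes of either size were recovered in these types.

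Named events were chosen by a rule fixed beforehand: among called events with libraries that did not overlap and at least 20 junction reads on average, 1 event per gene, the largest differences in each direction (10 skipped exons, 5 introns, 4 of each alternative splice site, 3 mutually exclusive exons), with every measured SRSF2 event and up to 4 called genes per gene list. The share of events whose libraries do not overlap was also taken, after the data were seen, as a mean over all 10 splits of the libraries, since tied levels cannot separate. Library means were compared by an exact permutation test of 3 against 3. The 15 gene lists were compared with all other tested genes by Fisher's exact test and by 100000 permutations matched on the number of tested events, with Benjamini-Hochberg adjustment over lists. Exon features used exon coordinates, and GENCODE release 29 transcript sequences where the exon matched exactly, with 100000 resamples. Splice site sequences were not analysed here. Of 11051 gene symbols, 97.5% matched an Ensembl gene and 94.0% had a protein-coding transcript length.

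Alternatives fixed beforehand were other minimum read numbers and differences, other pseudocounts, limma on the inclusion level, the authors' adjusted p, 1 event per gene and leaving out each library in turn. The count models also named beforehand were not run, because the written design kept them for libraries with a column each. Alternatives added after the data were seen were the trend on total junction depth, a mean inclusion level between 0.05 and 0.95, empirical Bayes without the robust option, and gene lists and exon features by the authors' adjusted p. Junction depth per gene was also added after the data were seen: the total reads of the best covered skipped exon event of each gene with at least 20 reads per library, as log2 CPM, tested with limma. In simulated data for 8238 genes that test recovered 58% of changes of 0.5 on the log2 scale and 100% of changes of 1, with 7.6% false calls. Every simulated gene had the same dispersion, and no shift was shared by the genes of a library. These shares therefore need not hold for the real libraries.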

Results

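RNA splicing was measured in MCF-7 cells, an oestrogen receptor positive human breast cancer line, in 6 RNA sequencing libraries. The study addressed how knockdown of SRSF2, a serine/arginine-rich (SR) protein that binds exons and promotes their inclusion, changes splicing. Titles divide the libraries into 3 named sh and 3 named u6. The labels disagree on which group is the knockdown: the genotype label calls the sh libraries the wild-type control and the u6 libraries the knockdown, while the design text sets an shRNA against SRSF2 beside a control. Groups are therefore named by their titles, every difference is sh minus u6, and no label was reassigned. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All 6 libraries carry batch label 1. Within a group, libraries are numbered by their place in the deposited cells, which may differ from the numbers in the titles.

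The deposited tables held 50343 skipped exon events, 2428 retained intron events, 8570 alternative 3' splice site events and 1216 mutually exclusive exon events. The alternative 5' splice site table was held only in part, with 689 complete events on 7 chromosomes, where the authors' deposited filtered list of that type covers 23. Junction reads over the skipped exon events numbered 11749153, 12192055 and 13187197 in the sh libraries and 14465271, 15374949 and 14835590 in the u6 libraries. Retained intron events had 299966 to 343719 junction reads in the sh libraries and 384249 to 405024 in the u6 libraries. The inclusion level is the length-corrected share of junction reads that support the longer form, from 0 to 1. No pair of libraries agreed within sampling noise: the mean chi-square per gene over the junction depth of 8238 genes ranged from 3.86 to 26.1.

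The targeted gene came first. SRSF2 had 5 measured retained introns on chromosome 17 of GRCh38, all in its 3' untranslated region and downstream of the coding sequence, between positions 76734563 and 76736153. The intron from 76735159 to 76736153 was retained at 0.328 ± 0.017 in sh and 0.221 ± 0.043 in u6 (SD, n = 3 each). Its retained junction reads were 124, 117 and 149 in sh and 99, 90 and 134 in u6, and its spliced reads were 136, 122 and 140 against 204, 184 and 180. Every sh library lay above every u6 library, and limma gave an adjusted p of 0.0574, which missed the threshold. The shorter intron from 76735159 to 76735771 was at 0.671 ± 0.021 in sh and 0.525 ± 0.104 in u6, with an adjusted p of 0.169 from limma. The intron from 76735876 to 76736153 was at 0.665 ± 0.094 and 0.542 ± 0.155, and its libraries overlapped. The intron from 76734563 to 76735060 differed by 0.030, and the one from 76734563 to 76736153 was retained at 0.997 in sh and 1.000 in u6. None of the 5 was called. Adjusted over the list alone, that is over these 5 introns, 2 passed, and without u6 library 3 there was 1 call.

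**Figure D1:**
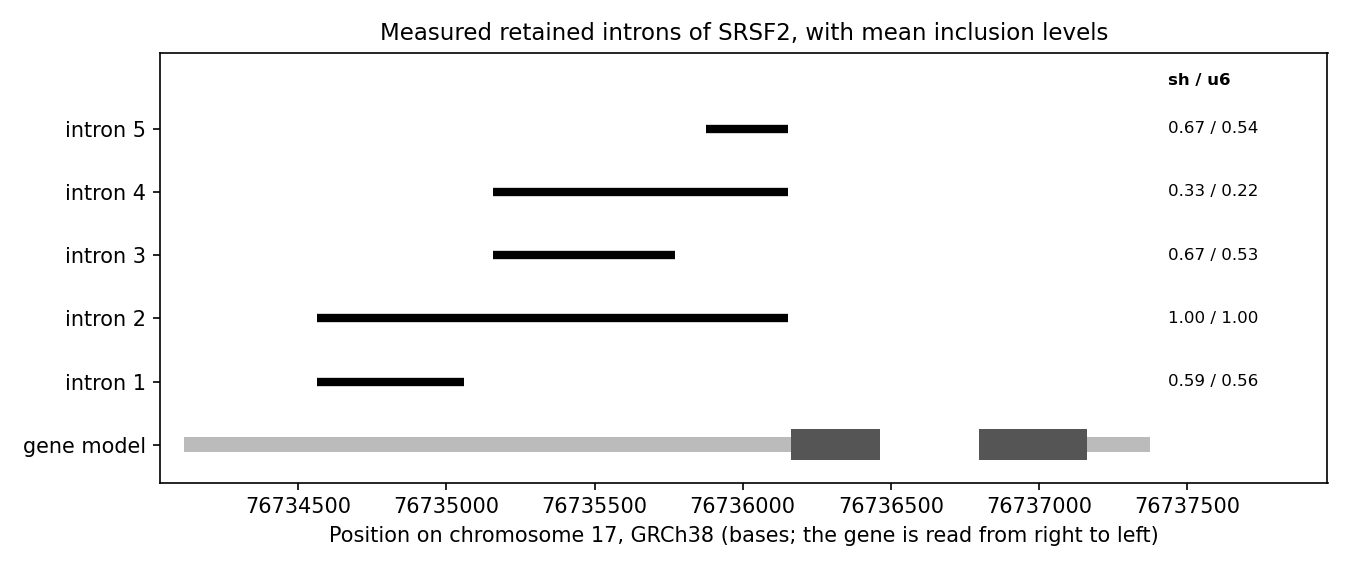
The 5 measured retained introns of SRSF2 on chromosome 17 (GRCh38, x axis in bases) above the gene model, with exons in light grey and coding sequence in dark grey. Numbers at the right are mean inclusion levels of the sh and u6 libraries (n = 3 each), and all 5 introns lie left of the coding sequence, which is the 3' side of this minus-strand gene.

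The intron from 76735159 to 76736153 was covered by 22.1, 19.6 and 21.9 CPM (retained and spliced reads relative to all skipped exon junction reads of the library) in sh and by 20.95, 17.8 and 21.2 CPM in u6. These ranges overlap. This is not a measure of the SRSF2 level, because the intron that splits its coding sequence is not among the measured events. In the authors' deposited table, the introns ending at 76736153 and 76735771 that start at 76735159 had differences of 0.107 and 0.146 with adjusted p of 0.00118 and 0.0465. The authors' deposited filtered list also held an alternative 5' splice site of SRSF2 from 76735061 to 76736153, with a difference of 0.066 and an adjusted p of 0.0046.

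Introns were retained more in the sh libraries. Over 1838 introns with a value in every library, the mean inclusion level was 0.507 ± 0.0055 in sh and 0.479 ± 0.0041 in u6 (SD, n = 3 each). The single values were 0.502, 0.508 and 0.513 against 0.481, 0.475 and 0.482, so that the groups did not overlap. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Of 1841 tested introns, 322 (17.5%) had libraries that did not overlap between groups, where chance gives 10% of events without ties and 8% with the ties present, as the mean over all 10 splits of the libraries. Of these, 273 were higher in sh and 49 lower. At adjusted p below 0.05 and a difference of at least 0.1, limma called 21 introns in 17 genes, of which 20 were higher in sh (95.2%, exact 95% interval 76.2 to 99.9%).

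**Figure D2:**
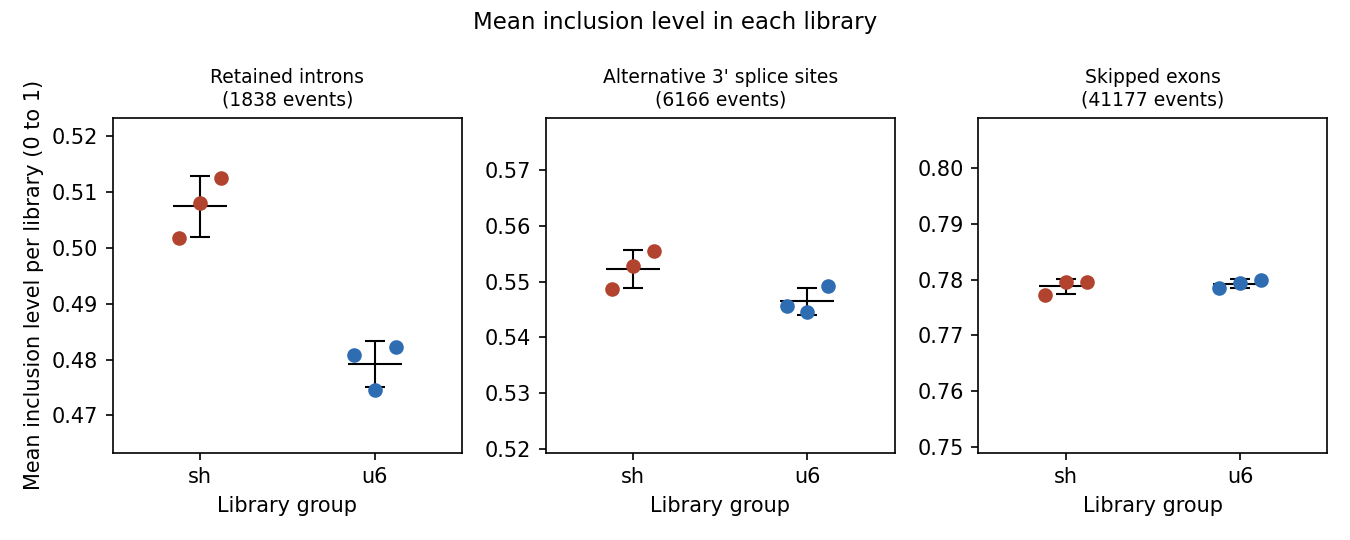
Mean inclusion level (y axis, 0 to 1, each panel spanning the same range of values) in each library over retained introns, alternative 3' splice sites and skipped exons. Points are libraries, bars are the group mean and SD (n = 3), and the groups are apart for retained introns (0.502 to 0.513 in sh, 0.475 to 0.482 in u6) and overlap for the other panels.

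Among called introns with at least 20 junction reads per library on average, the largest rises, taking 1 intron per gene, lay in LUC7L, DAB2IP, OGT, IP6K2 and RSRP1. Below that minimum, and named here after their values were seen, introns of GPX1 (0.630, 10.7 reads) and RRAGB (0.437, 13.2 reads) rose by more than that of LUC7L (0.394). In LUC7L, which encodes a protein associated with the U1 particle, which recognises 5' splice sites, the intron at chromosome 16, 227337 to 228332, was retained at 0.657 ± 0.118 in sh and 0.262 ± 0.071 in u6 (adjusted p = 0.00143 from limma). In OGT, which encodes the enzyme that attaches N-acetylglucosamine to intracellular proteins, the intron at chromosome X, 71544636 to 71547906, was at 0.787 ± 0.056 and 0.476 ± 0.141 (adjusted p = 0.000386). The DAB2IP intron at chromosome 9, 121782402 to 121783535, was at 0.850 and 0.509. The IP6K2 intron at chromosome 3, 48694825 to 48695089, was at 0.567 and 0.259. The RSRP1 intron at chromosome 1, 25243634 to 25245149, was at 0.625 and 0.346. RBM39, a U2AF-related splicing factor, had an intron at chromosome 20, 35739018 to 35740524, at 0.438 ± 0.059 and 0.305 ± 0.063 (adjusted p = 0.0197). The only called intron that was lower in sh lies in untranslated sequence of SRSF1, the founding SR protein, at chromosome 17, 58004002 to 58004922. It was retained at 0.721 ± 0.063 in sh and 0.881 ± 0.055 in u6, over 820 junction reads per library (adjusted p = 0.0032). Another SRSF1 intron, at 58005601 to 58005800 and named here after its values were seen, was higher in sh, at 0.186 ± 0.063 and 0.075 ± 0.023 (adjusted p = 0.00287). All 21 introns were also below 0.05 by the authors' adjusted p.

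The number of called introns rested on the model. The design fixed before the data were examined asked for a variance trend on junction depth and did not say of which form. The depth of the rarer form was taken before any test was run. A trend on total junction depth, the plainer reading of those words, called 0 introns, as did limma on the inclusion level itself, while 266 introns had an unadjusted p below 0.05. In data simulated with the same depths, the rarer-form trend recovered 83% of introns changed by 0.3 and 40% of those changed by 0.2, with 0.8% false calls, and the total-depth trend recovered 0%. These changes were planted only in introns with intermediate inclusion levels and at least 20 junction reads on average. The simulation therefore does not settle which trend is right for other introns. Leaving out 1 library gave 36 calls without sh library 1, 11 without sh library 2, 9 without u6 library 2 and 38 without u6 library 3.

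Called alternative 3' splice sites were mostly higher in sh, in part over the same reads as called introns. Of 6172 tested events, 23 in 18 genes were called by limma, 19 with more of the longer form in sh and 4 with less (82.6% higher, exact 95% interval 61.2 to 95%). The libraries of 621 events (10.1%) did not overlap, against 10% by chance without ties and 7.6% with the ties present, and 396 of these were higher in sh. The mean inclusion level was 0.552 ± 0.0034 in sh and 0.547 ± 0.0024 in u6, and the libraries overlapped (SD, n = 3 each, two-sided exact permutation p = 0.2). SRRM2, a large SR-related protein of the spliceosome, had 4 called events on chromosome 16. They are not separate measurements: 3 of them share their skipping reads with a called SRRM2 intron, and 2 called introns overlap these 3. In the event with the smallest adjusted p, the region from 2769628 to 2770351, outside annotated coding and untranslated sequence, was included at 0.461 ± 0.047 in sh and 0.199 ± 0.063 in u6 (adjusted p = 5.49e-15 from limma). In SRSF6, an SR protein, the region at chromosome 20, 43459153 to 43459770, was included at 0.498 ± 0.053 and 0.309 ± 0.047 (adjusted p = 0.00034). The OGT region at chromosome X, 71544567 to 71547906, overlaps its called intron, shares its skipping reads and was at 0.542 and 0.247. Called sites of RRAGB and WSB1 (WSB1 named here after its values were seen) also share their skipping reads with a called intron of the same gene. The calls of OGT, RRAGB and WSB1 are therefore not separate from the intron calls. SLC25A29, RIMKLB and DNASE1L1 rose by 0.534, 0.440 and 0.340, the largest among called events with at least 20 junction reads per library on average and libraries that did not overlap. Outside those limits, and named here after their values were seen, RABL2A rose by 0.538 and RRAGB by 0.403 over 12 reads each, and SCML1 rose by 0.425 with overlapping libraries. CCNL1, a cyclin that associates with splicing factors, was at 0.486 and 0.339, with overlapping libraries and 0.0766 by the authors' adjusted p in their deposited table. Lower inclusion in sh was called in MKNK2, a kinase that phosphorylates the cap-binding protein eIF4E and is a known target of SRSF1, where the region at chromosome 19, 2037830 to 2039856, was at 0.203 ± 0.035 and 0.344 ± 0.080 (adjusted p = 0.00154). The SMARCA4 site at chromosome 19, 10984121 to 10984123, was at 0.479 and 0.773, with overlapping libraries. C17orf49 (-0.576, 10.7 reads) and BANP (-0.398, 18.5 reads, overlapping libraries) were also lower in sh, both named here after their values were seen. Their differences rested on single libraries: that of C17orf49 was -0.381 without sh library 1, and that of BANP was -0.211 without sh library 2. A trend on total junction depth and limma on the inclusion level each called 0 of these events, with 513 at an unadjusted p below 0.05, and 1 event per gene left 3 calls. Leaving out u6 library 1 or u6 library 2 left 14 and 13.

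**Figure D3:**
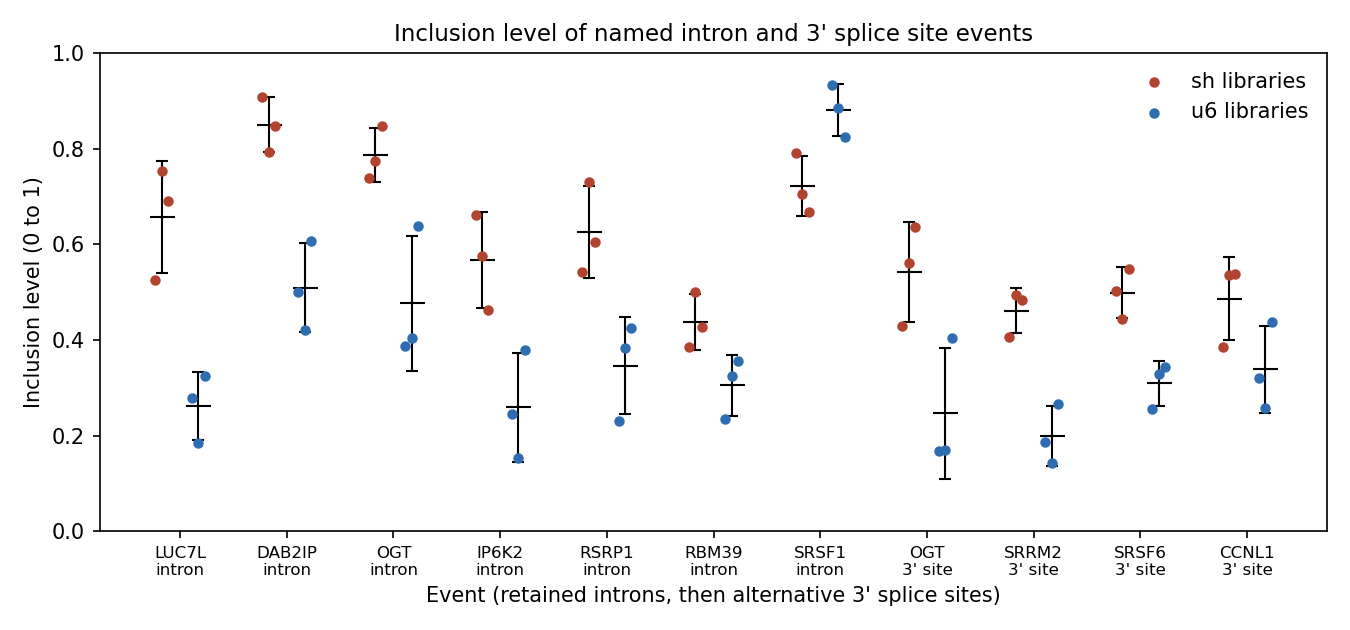
Inclusion level (y axis, 0 to 1) in each library of the retained introns named by the rule, without those of SRSF2, and of the SRRM2, SRSF6, OGT and CCNL1 3' splice sites. The named 3' splice sites that were lower in sh (MKNK2 and SMARCA4) and those with the largest rises (SLC25A29, RIMKLB and DNASE1L1) are not shown. Points are libraries, bars are the group mean and SD (n = 3), and every event shown but the SRSF1 intron is higher in sh, with overlapping libraries in CCNL1. The choice of the 3' splice sites shown means that their direction is not a result.

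Skipped exons changed in both directions. Of 41218 tested events, limma called 37 in 36 genes, 20 with more inclusion in sh and 17 with less (54.1% higher, exact 95% interval 36.9 to 70.5%). 1 of the 20, an exon of LOC102724560 named here after its values were seen, averaged 14 reads, with levels of 0, 1 and none in sh. Its difference of 0.486 became -0.014 without sh library 2. Without the minimum difference 70 passed, of which 33 were higher (47.1%). In simulated skipped exons with no changed event 56 passed in this way, so neither the 70 nor their direction can be told from no change. The mean inclusion level was 0.779 ± 0.0014 in sh and 0.779 ± 0.0008 in u6 (SD, n = 3 each, two-sided exact permutation p = 0.7). The median was 0.991 to 0.992 in sh and 0.993 to 0.994 in u6, so that these did not overlap (two-sided exact permutation p = 0.1, the smallest possible). The libraries of 2369 events (5.7%) did not overlap between groups, of which 1147 were higher in sh. Chance gives 10% without ties, but 78.9% of these events had tied levels, and with them it gives 4.4%. In CLSTN1, which encodes calsyntenin-1, the 57-base exon at chromosome 1, 9737498 to 9737554, was included at 0.493 ± 0.047 in sh and 0.323 ± 0.006 in u6 over 330 junction reads per library (adjusted p = 2.75e-05 from limma). The 27-base coding exon of MARK3, a kinase of microtubule-associated proteins, at chromosome 14, 103498502 to 103498528, was at 0.710 ± 0.110 and 0.269 ± 0.235. TATDN1 was at 0.792 and 0.359, ST7L at 0.837 and 0.352, and MIGA2 at 0.650 and 0.238. SLC25A51, the mitochondrial NAD carrier, was at 0.782 and 0.393. MICOS10, a subunit of the complex that shapes mitochondrial cristae, was at 0.884 and 0.518. NT5C2 was at 0.638 and 0.322, but its difference of 0.316 fell to 0.178 without sh library 2 (adjusted p = 0.912 from limma), and the authors' adjusted p in their deposited table was 0.258. MBD1, which binds methylated DNA, was at 0.550 and 0.295 (0.0604 by the authors' adjusted p in their deposited table), and TRAF2, an adaptor of tumour necrosis factor receptors, at 0.190 and 0.016.

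Lower inclusion in sh was led by GMPR2, a guanosine monophosphate reductase, whose exon at chromosome 14, 24234107 to 24234241, was at 0.321 ± 0.079 in sh and 0.660 ± 0.088 in u6 (adjusted p = 0.00476 from limma). MIA3, which loads collagen into transport vesicles, was at 0.205 ± 0.006 and 0.435 ± 0.123 for the exon at chromosome 1, 222644329 to 222644586. The exon of the noncoding host gene SNHG6 at chromosome 8, 66922324 to 66922385, was at 0.530 ± 0.027 and 0.691 ± 0.051 over 292.7 junction reads per library. LY6K, ZC3H11A, SLC25A14, NUCB2, SNX24 and SPAG4 fell by 0.324, 0.323, 0.304, 0.275, 0.221 and 0.218. The ZC3H11A difference was -0.201 without u6 library 1 (adjusted p = 0.877 from limma), it was called in 1 of 6 fits that leave out a library, and the authors' adjusted p in their deposited table was 0.189. The untranslated exon of AKT1, a kinase of growth factor signalling, at chromosome 14, 104794144 to 104794261, was at 0.067 and 0.242. The exon of TRA2B at chromosome 3, 185931577 to 185931852, named here after its values were seen, was at 0.315 ± 0.023 in sh and 0.209 ± 0.050 in u6 (adjusted p = 0.00156). A trend on total junction depth and limma on the inclusion level each called 0 skipped exons, with 2290 at an unadjusted p below 0.05 (1013 higher and 1266 lower in sh), and keeping only events with a mean inclusion level between 0.05 and 0.95 left 3. In simulated skipped exons 8.3% of calls were false, and 2 were called with no changed event. The other splits of the 6 real libraries into 3 and 3 called 2 to 14, so the true share may be higher than 8.3%. Leaving out u6 library 2 left 24 calls. Of the 39 named called events of all types, 3 (the CLSTN1 exon, the OGT intron and the SRRM2 site) were called by limma without each library in turn, and every other lost its call without at least 1 library.

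Of 481 tested alternative 5' splice site events, 1 was called, with 37 at an unadjusted p below 0.05. The region of U2AF1L4, a relative of the small U2AF subunit, at chromosome 19, 35744012 to 35744069, was included at 0.035 ± 0.033 in sh and 0.160 ± 0.052 in u6 (adjusted p = 0.0324 from limma). It lost its call without sh library 1 or 3 and without u6 library 2 or 3. Of 936 mutually exclusive exon events, 2 were called, both higher in sh. PRKAR1A, a regulatory subunit of protein kinase A, used the untranslated exon at chromosome 17, 68512379 to 68512579, at 0.222 ± 0.046 in sh and 0 in u6, over 30 junction reads per library. The same exon is also among the called skipped exons, with the same inclusion reads (7, 10 and 5 in sh and 0 in each u6 library). These 2 calls are not separate measurements. GTPBP10 used the coding exon at chromosome 7, 90354458 to 90354549, at 0.743 ± 0.044 and 0.518 ± 0.101. Calls of mutually exclusive exons rose to 4 without sh library 2 and fell to 1 without sh library 3 or u6 library 1, and without the robust option there were 0.

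Among the 15 gene lists fixed before the data were examined, called events were concentrated in the SR proteins and their relatives. Of 28 tested genes, 6 had a call (LUC7L, SRRM2, SRSF1, SRSF11, SRSF6 and TRA2B), or 21.4% against 0.67% of other genes (Fisher's exact test, adjusted p = 6.21e-07). A permutation matched on the number of tested events expected 0.35 genes and gave an adjusted p of 0.00015, the smallest it can give. These genes held 14 called events, 13 of them higher in sh and 6 of them overlapping or neighbouring events of SRRM2, and 21 events in 7 genes passed when adjusted over the list alone. The called events of SRSF11 also share their skipping reads, and those of SRSF6 lie at the same region. The 14 are therefore not separate measurements of direction. Most of the 14 were introns or 3' splice sites: with skipped exons alone only TRA2B counted, and the adjusted p was 0.51. By the authors' adjusted p, 11 of the 28 genes counted (adjusted p = 0.0028). Over these sets of calls Fisher's adjusted p ranged from 6.21e-07 to 0.51, and that of the matched permutation from 0.00015 to 0.683. Both were highest with skipped exons alone. A trend on total junction depth and limma on the inclusion level called none of the 14 events. The lists were not tested with those calls. Both tests count genes and leave out the spread between libraries, and neither was matched on read depth. The core spliceosome had 2 called genes of 71 (RBM39 and U2AF1L4, adjusted p = 0.478), the exons regulated in epithelial-mesenchymal transition 2 of 49 (CLSTN1 and MARK3, 0.375) and the chromatin regulators 2 of 106 (MBD1 and SMARCA4, 0.561). Reported targets of SRSF2 or of its mutants had 1 called gene of 42 (SRSF1, adjusted p = 0.665), cell cycle regulators 1 of 61 (CCNL1, 0.778) and luminal breast and oestrogen receptor genes 1 of 28 (AKT1, 0.561). No call fell on the 24 tested hnRNP genes, 14 splicing kinases, 22 genes of nonsense-mediated decay, 37 apoptosis regulators, 80 DNA repair genes, 42 other splicing regulators or 6 markers of other cell types. Adjusted over the list alone, events of MAGOH and UPF3A in the decay list, of AURKB among cell cycle regulators, of EXOC7 among the transition exons and of SRSF2 among the other splicing regulators also passed, and none did among hnRNP genes, splicing kinases, apoptosis regulators, DNA repair genes or markers of other cell types.

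Called skipped exons were compared with the tested exons that were not called. Their median length was 93 bases against 117, and 43.2% against 39.8% had a length that is a multiple of 3 (permutation test with 100000 resamples, adjusted p = 0.743 for both). The density of CCNG and GGNG motifs, which SRSF2 is known to bind, was 4.96 ± 4.49 per 100 bases in 30 called exons and 3.74 ± 2.79 in 29329 others (unadjusted p = 0.0169, adjusted p = 0.0676). With 325 exons called by the authors' adjusted p, it was 3.86 against 3.74 (permutation test, unadjusted p = 0.452), and over the alternatives the adjusted p was 0.0648 to 0.452. GC content was 50.3% and 49.0% (adjusted p = 0.743). No feature passed the threshold.

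The authors' deposited filtered lists were longer. They held 1070 skipped exons (534 higher and 536 lower in sh), 261 retained introns (216 and 45), 422 alternative 3' splice sites (271 and 151), 384 alternative 5' splice sites (246 and 138) and 27 mutually exclusive exons (14 and 13). Every listed event had an adjusted p below 0.05, and the smallest differences in the authors' deposited lists were 0.011 to 0.048. The calls made here were in these lists for 31 of 37 skipped exons, 21 of 21 introns, 21 of 23 alternative 3' splice sites, 1 of 1 alternative 5' splice site and 2 of 2 mutually exclusive exons.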

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

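The trend on total junction depth, the limit on the mean inclusion level, empirical Bayes without the robust option, and the measure of junction depth per gene with its alternatives were chosen only after the data were seen, as were the tests of gene lists by the authors' adjusted p. No paired analysis was possible because the libraries of a group are joined in a cell with no numbers that tie them to the titles. The count models named beforehand were not run, because the written design kept them for libraries with a column each.

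The counts of called events depended on the model. For skipped exons, 37 in the report, the count was 59 at a difference of at least 0.05, 20 at 0.2, 410 by the authors' adjusted p, 0 with limma on the inclusion level, 0 with a trend on total junction depth and 3 with a mean inclusion level between 0.05 and 0.95. Leaving out each library in turn gave 24 to 40. For retained introns, 21 in the report, it was 13 at a difference of at least 0.2, 120 by the authors' adjusted p, 0 with limma on the inclusion level, 11 with a pseudocount of 0.1, 13 with 1 event per gene, 0 with a trend on total junction depth and 9 to 38 without each library. For alternative 3' splice sites, 23 in the report, it was 15 at 0.2, 158 by the authors' adjusted p, 0 with limma on the inclusion level, 4 with a pseudocount of 0.1, 3 with 1 event per gene, 0 with a trend on total junction depth, 4 with a mean inclusion level between 0.05 and 0.95 and 13 to 29 without each library. For alternative 5' splice sites, 1 in the report, it was 13 by the authors' adjusted p, and 0 with no junction read minimum, a minimum of 20, a difference of 0.2, limma on the inclusion level, a pseudocount of 1 or 0.1, 1 event per gene, a trend on total junction depth, a mean inclusion level between 0.05 and 0.95, or without the robust option. It was 0 to 1 without each library. For mutually exclusive exons, 2 in the report, it was 14 by the authors' adjusted p, 1 with limma on the inclusion level, 1 with a trend on total junction depth, 0 with a mean inclusion level between 0.05 and 0.95, 0 without the robust option and 1 to 4 without each library. A larger or smaller minimum difference changes a count by its own construction, and for the other changes the cause was not tested.

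The difference of mean intron retention was 0.0282 in the report, 0.022 with at least 50 junction reads and 0.0256 to 0.031 without each library. Of SRSF2 introns 0 were called in the report, 2 passed by the authors' adjusted p, and 0 to 1 without each library. Of the gene lists 1 passed in the report and 0 with skipped exons alone, where 1 gene of the SR protein list was called. Genes called for junction depth numbered 1075, 392 with transcript length and GC content removed, and 2 to 2382 without each library. Of the 39 named called events, 3 were called without each library in turn, 1 with a trend on total junction depth, 0 with limma on the inclusion level, 7 with a mean inclusion level between 0.05 and 0.95 and 35 by the authors' adjusted p.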

Other observations

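The tests of a wrong label, of a swap and of the splits for splicing events were chosen only after the results they bear on were seen, and junction depth per gene was added as a measure after the data were seen. The difference between the groups that the titles name is the biological explanation, and it stays open and untested for each pattern.

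Junction depth, a stand-in for transcript level at the best covered skipped exon event of a gene, also differed between the groups. Of 8238 genes, limma called 1075, with 854 higher in sh and 221 lower. Among the largest rises, named here after their values were seen, DICER1, the ribonuclease that makes microRNAs, was at 3.57, 3.12 and 2.27 CPM in sh and 0.35, 0.33 and 2.22 in u6, and AKAP11, an anchor of protein kinase A, was at 5.53, 5.41 and 6.45 against 0.76, 1.5 and 3.3. SMIM11 had the largest fitted rise (3.94), but it was at 9.96, 0.66 and 10.46 CPM in sh and 0.48, 0.07 and 0.4 in u6, so that it rested on sh libraries 1 and 3, and a near-identical copy makes its reads uncertain. PEAK1, CRYBG3 and REV3L rose by 1.96, 1.82 and 1.79 on the log2 scale. Lower depth was called in GFER (-0.91), NAGLU (-0.96) and DNAJC4 (-0.97). Of the lists, SR proteins had 11 of 27 genes higher, the transition exons list 17 of 47, chromatin regulators 21 of 103 and the core spliceosome 16 of 67, with none lower in these lists. With a preset correlation camera gave these lists adjusted p of 0.00326, 0.000203, 0.000139 and 0.0213, but with an estimated correlation no list passed (adjusted p = 0.616 for each of these). With transcript length and GC content removed no list passed either (adjusted p of 0.861 to 0.865). The count rested on single libraries: without sh library 1, 2 or 3 it was 196, 231 and 2, and without u6 library 1, 2 or 3 it was 174, 3 and 2382.

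Intron retention was higher in sh (median log2 change of the retained to spliced ratio 0.391 over all introns). Reads from genomic DNA would add about equally to every intron and move well covered ones least. In the 614 introns with most retained reads the median was 0.194 (bootstrap 95% interval 0.112 to 0.262). The interval lies narrowly above the bound of 0.1 set beforehand, but that bound was not derived from an amount of DNA. The bootstrap, here and below, drew genes and not libraries, so its intervals leave out the spread between libraries. For these reasons the test cannot decide on DNA. The median is lower than 0.391, as DNA would also make it, so DNA stays open. In the 598 introns of genes with the shortest transcripts it was 0.407 (0.339 to 0.499), which argues against the transcript length trend. Of 10 splits of the 6 libraries only the real one (1) gave as many as 21 calls, with a highest other count of 0, and 10 splits are too few for a share under 0.05. Among alternative 3' splice sites with an unadjusted p below 0.05, 74.3% of those that overlap a measured retained intron were higher in sh, and so were 60.1% (54.8 to 65.1%) of the 368 that do not. Overlap with the measured introns therefore does not account for all of that direction. Introns that were not measured could still add to it, and the interval counts events, which are not independent.

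Junction depth in sh rose with transcript length, from a median log2 change of -0.136 in the shortest of 5 length classes to 0.446 in the longest. Lost 5' ends in u6 would give a trend within genes, yet the median within-gene slope was 0.0004 per kb from the 3' end (-0.0066 to 0.0065, 1745 genes) against 0.0671 per kb between genes. With GC content in the model the slope per doubling of length was 0.1748 (0.1663 to 0.1832), down from 0.2237, so GC content accounts for a part at most. Of 10 splits only the real one (1) gave as many as 1075 genes, with a highest other count of 0, which is too few splits for a share under 0.05. Fragment selection and a true difference of the groups stay open.

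Library 3 of u6 lay towards the sh libraries. Its junction depth correlated at 0.9762 to 0.9786 with the sh libraries and at 0.9684 and 0.9768 with the other u6 libraries (across 8238 genes, which are not independent replicates). On a scale from u6 libraries 1 and 2 (0) to the sh libraries (1), its median place was 0.476 (0.375 to 0.576) over 99 events called without it. This cannot decide on a wrong label. The events were picked for a gap between the other libraries, which pulls any library left out below 1. The place of an sh library left out in the same way was not measured. The mean chi-square per gene of u6 library 3 was 6.49 to 7.45 with the sh libraries. It was 12.08 with u6 library 1 and 8.2 with u6 library 2. Every sh library correlated more with the other sh libraries than with u6 libraries 1 and 2, by at least 0.0172, which argues against a swap. Over 2382 genes whose depth differed without u6 library 3, its median place was 0.642 (0.629 to 0.656) on the log2 scale. This lies apart from 0.476, but mixing acts on the linear scale, where it was 0.583 (0.569 to 0.595) and the intervals overlap, so the bound set beforehand on the log2 scale was wrong and sh RNA in this library cannot be told apart from a weaker effect in it.

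In the other event types only the real split (1 of 10) gave as many calls as the groups did: 37 skipped exons against a highest other of 14, 23 alternative 3' splice sites against 3, 1 alternative 5' splice site against 0 and 2 mutually exclusive exons against 1. With 10 splits no share under 0.05 can be had.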
